A study of Drosophila melanogaster with 7 samples.

How the data were processed

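RNA sequencing was done on 7 libraries of larval central nervous system, 3 control (elav-GAL4 alone) and 4 with elav-GAL4 driving a hairpin against Iswi, each described in the labels as a biological replicate of about 40 brains. Libraries were made with a strand-specific kit and read as single reads of 100 bases, per the labels' protocols. Reads were aligned with STAR 2.5.0b to build BDGP6 and compared with DESeq2, per the submitters' processing notes. How reads were assigned to genes, and whether strand was used in counting, is not given in the sources used here, so genes that overlap a neighbour or share reads with a near-identical copy are uncertain.

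What was analysed is the authors' deposited comparison, with 1 row per gene. Per the file headers it gives a base mean, a signal that is the mean of the counts after division by the authors' size factors over all libraries. It also gives the authors' log2 fold change of ISWI knockdown over control, with the p-value and the adjusted p-value the authors deposited for each gene. The column header calls the control attp2, while the labels describe it as the driver alone. The table holds 2366 genes, and each has a p under 0.1, so it is the part of the comparison with p under 0.1. The adjusted p-values deposited by the authors follow the Benjamini-Hochberg rule over 10775 tests, which was worked out from p, rank and adjusted p. On that count 8463 tested genes (p of at least 0.1) are not analysed here, and the table holds 21.5% of those tested. A further 54 genes with a mean count of at most 2.43 have an adjusted p of 1 and were left out of the tests. Values per library were not used here, so depth per library is unknown, no model was refitted, and the test planned for counts gave way to the planned reading of the deposited comparison.

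A gene was called higher or lower when the authors' adjusted p was under 0.05. A standard error was worked out from each log2 fold change and p-value, taking the authors' p as that of a Wald test, and 95% intervals use it. It is the authors' error, not a new estimate. Precision followed the mean count, with a Spearman rho of -0.936 between implied standard error and mean count across listed genes, which are not independent replicates. The median implied standard error was 0.60 for listed genes with a mean count under 50 and 0.06 for those over 5000, and the smallest log2 fold change called fell from 0.96 to 0.15 between those classes.

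Before the data were examined, 38 gene lists, the tests, the alternatives and the rule for named genes were fixed. The rule took Iswi, the 12 highest and 12 lowest log2 fold changes among calls with a mean count of at least 50, and up to 4 members of each list with the smallest adjusted p. The lists cover ISWI complexes, other remodellers, Polycomb and trithorax, Hox, neuroblast, temporal and cell cycle genes, neuronal, transmitter, receptor, peptide, channel, clock, guidance, surface protein and mushroom body genes, Notch, ecdysone, activity, stress, heat shock and immune genes, histone variants, dosage compensation, and glia. They also cover hemocytes, fat body, muscle, ring gland, salivary gland, imaginal disc, eye disc and trachea, ribosomal proteins, respiratory chain, marker genes, and chromosomes X and 4. A gene can be in more than 1 list. Directions were compared by a two-sided Fisher's exact test of higher against lower calls inside and outside a list, for lists with at least 5 members in the table, with Benjamini-Hochberg adjustment over lists. A ranked test (cameraPR) had been planned for a table of all genes and was not run, because a table that ends at p under 0.1 has no middle of the ranking. After the table was seen, the same Fisher test on all listed genes was added, and a one-sided hypergeometric test of how many members are listed, which takes every matched member as tested and is conservative for that reason. Because lower calls were more frequent among abundant genes, an exact direction test within 5 classes of mean count (limits 50, 200, 1000 and 5000) was added too, for lists, noncoding RNAs and the X. Counts "adjusted over the list alone" treat members not listed as not passing. Calls on X were compared with those on 2L, 2R, 3L and 3R.

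Of the gene identifiers 2345 were in the reference annotation of the same assembly and 2322 had the same chromosome, start and end there. For 9 identifiers with no symbol in the table, 8 took a symbol from the reference, and missing positions were filled from it. The list tests were tested on simulated data, 20 tables of 10775 genes with lists of 30 members. Lists made with a shift were found in 100% of cases by both tests, and random lists were called in 0.167% (direction) and 2.5% (hypergeometric) of cases. That power does not carry over to the real lists, most of which hold under 5 calls. Nor do the rates for random lists. The simulated genes varied independently, and these simulated tests used calls only, not all genes listed at p under 0.1. In 50 simulated tables of 2300 genes, direction changed by a step at the lower limit of the top class of mean count. Lists of abundant genes were called in 94% of cases by Fisher's test and in 2% within classes. With the step at a class limit no trend was left inside a class, so that low rate was fixed beforehand. The real share of higher calls fell from class to class, and the top class has no upper limit. The run therefore does not show that classes remove the real effect of mean count. Python 3.11.15 was used with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9. Alternatives were a stricter and a looser threshold, a minimum fold change, a Bonferroni adjustment, a minimum mean count, and for lists and the X all listed genes or classes of mean count.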

Results

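The series measured RNA from the dissected central nervous system (central brain and ventral nerve cord) of Drosophila melanogaster larvae in the middle of the third larval instar, 4 days after egg lay at 25 °C. In 4 libraries the larvae carried elav-GAL4, a driver active in neurons throughout the nervous system, together with a UAS hairpin against Iswi, the ATPase of the ISWI family of nucleosome remodelling complexes. The 3 control libraries came from larvae with the driver and no hairpin. Each library pooled about 40 brains and was read as single reads of 100 bases. The comparison asks which transcripts differ in the larval nervous system when ISWI is knocked down in neurons. The values come from the authors' deposited table, which holds 1 fold change per gene and lists genes with a p under 0.1. Values per library were not used here, so the depth of each library is unknown and the spread between libraries enters only through the authors' p.

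Iswi RNA fell by 2.03 on the log2 scale in the authors' deposited table (FBgn0011604, chromosome 2R, 12636671 to 12640628, build BDGP6). That left 24.6% of the control level at a mean normalised count of 3543, with an adjusted p of 5.1e-230 and a standard error of 0.06 implied by that table's p. The next smallest adjusted p belonged to dsx-c73A, which fell by 5.02 on the log2 scale in the authors' deposited table. CG15930 and KFase (kynurenine formamidase) came next in the authors' deposited table and rose by 5.72 and 4.46. Among the 501 genes of the authors' deposited table with an adjusted p under 0.05, 222 were higher and 279 lower with the knockdown, out of 10775 genes that its adjusted p values imply were tested. The higher genes of that deposited table had a median change of 1.65-fold and a median mean count of 168, and the lower ones a median change of 1.30-fold and a median mean count of 946. A change of at least 1 on the log2 scale was found for 89 higher and 32 lower genes of the authors' deposited table.

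**Figure D1:**
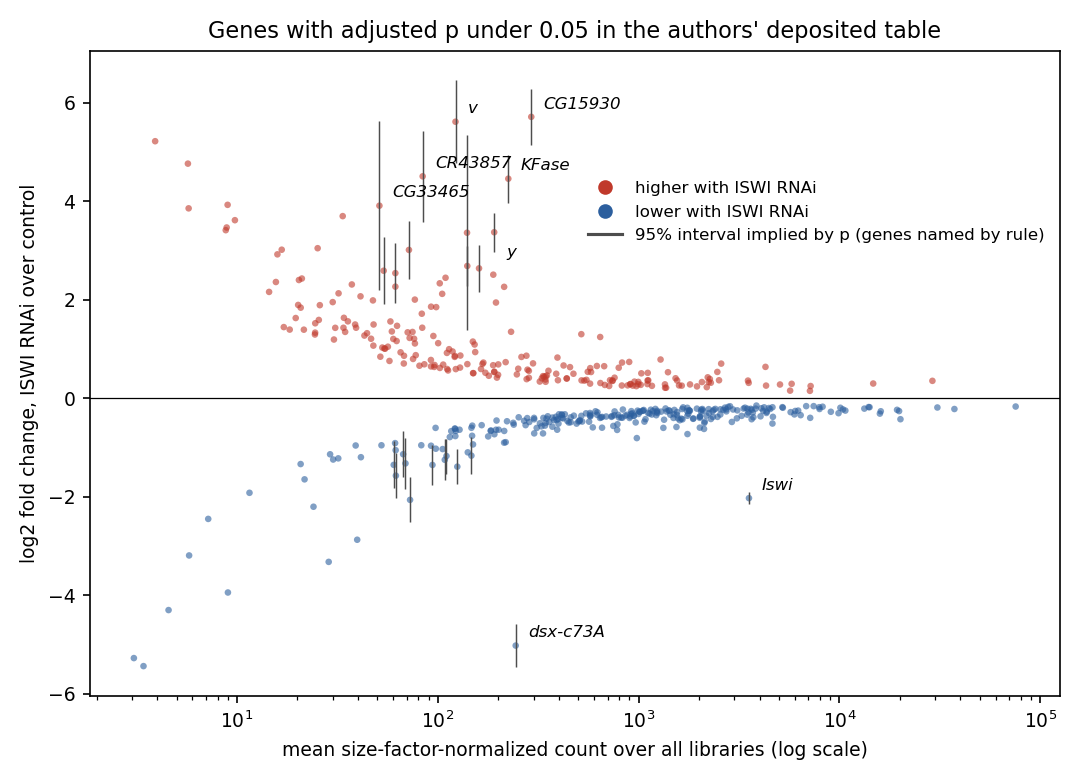
Log2 fold change (ISWI RNAi over control, vertical axis) against the mean size-factor-normalised count (horizontal axis, log scale) for the 501 genes with an adjusted p under 0.05 in the authors' deposited table, 222 higher in red and 279 lower in blue. Vertical lines are 95% intervals implied by the deposited p for the genes named by rule, and Iswi stands at -2.03 with a mean count of 3543.

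The highest fold change among genes with a mean count of at least 50 belonged to CG15930 (chromosome X, 5315130 to 5317295), which rose by 5.72 on the log2 scale in the authors' deposited table (implied standard error 0.29, adjusted p 4.8e-82). v (vermilion, tryptophan dioxygenase) rose by 5.62 in the authors' deposited table (chromosome X, 10923972 to 10925631, implied standard error 0.43, adjusted p 1.2e-35), and KFase lies on chromosome 2L (6487342 to 6488756, adjusted p 1.3e-69). The pigmentation gene y (yellow) rose by 3.37 in the authors' deposited table, with an adjusted p of 3.3e-60. y and v are common visible markers in fly stocks and transgenes. Each group here is 1 genotype, so their values cannot be assigned to the knockdown rather than to the stocks. The same limit holds for other calls, such as CG15930, KFase and dsx-c73A. Cyp4g1, a cytochrome P450 of cuticular hydrocarbon synthesis, rose by 3.36 in the authors' deposited table, but with an implied standard error of 1.01 and an adjusted p of 0.024. CG33465 rose by 3.91 with an adjusted p of 4.5e-04 in the authors' deposited table. corolla, a synaptonemal complex component of meiotic cells, rose by 2.69, and CG30424 by 2.54, in the authors' deposited table. The other 4 genes of the highest 12 in the authors' deposited table were noncoding RNAs, CR43857, CR45181, CR43459 and CR45054, with log2 fold changes of 4.51, 3.01, 2.64 and 2.59. Across the authors' deposited table, 29 of 42 noncoding RNA calls were higher, against 190 of 448 protein-coding calls (Fisher's exact test, two-sided, p = 0.00106). Noncoding calls had a median mean count of 94.5 against 573 for protein-coding calls in the authors' deposited table. Calls at low counts were mostly higher there, 44 of 61 with a mean under 50 against 7 of 36 over 5000. Within classes of mean count the noncoding RNAs did not differ in direction from the protein-coding genes past the threshold (24.9 expected higher, exact test, p = 0.154).

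In the other direction dsx-c73A (chromosome 3L, 16422795 to 16451958) fell by 5.02 on the log2 scale in the authors' deposited table, to 3.09% of the control level (implied standard error 0.22, adjusted p 1.3e-109). Spn47C, a serpin, fell by 2.06 in the authors' deposited table, close to Iswi itself. CG15047, the DEG/ENaC channel gene rpk (ripped pocket), CG13029 and prim had log2 fold changes of -1.57, -1.39, -1.35 and -1.25 in the authors' deposited table. SoYb and AGO3, which act in the piRNA pathway, fell by 1.16 and 1.13 in the authors' deposited table, with adjusted p of 1.6e-07 and 1.3e-04. The noncoding RNAs CR43425 and CR44029, both on chromosome 4, and CR43242 on 2L completed the lowest 12 of the authors' deposited table, at -1.35, -1.32 and -1.17.

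Of 22 pan-neuronal genes, 42 transmitter receptors, 28 ion channel genes and 8 Hox genes, 0 passed an adjusted p of 0.05 in the authors' deposited table, over all genes or adjusted over the list alone. The immunoglobulin-family surface proteins of the DIP, Dpr, Beat and Side families had 3 of 54 members higher and 0 lower in the authors' deposited table. These were DIP-zeta, beat-IIIc and dpr2, which rose by 0.83, 0.37 and 0.34 on the log2 scale in the authors' deposited table, and the same count of 3 held when adjusted over the list alone. Among all members listed at p under 0.1 in the authors' deposited table, 17 had a positive and 1 (dpr21) a negative fold change (Fisher's exact test against the other listed genes, two-sided, adjusted p = 0.000526 over 26 lists, and 1.9e-05 within classes of mean count). Of 45 axon guidance genes Dscam4 rose by 0.54 in the authors' deposited table, and 8 listed members were positive and 1 negative (adjusted p = 0.0435, Fisher's exact test, and 0.00389 within classes of mean count). Listed transmitter receptors showed the same split in the authors' deposited table, 8 positive and 1 negative (adjusted p = 0.0435, Fisher's exact test, and 0.0469 within classes of mean count). None of them was called, and Octbeta2R, at 0.27, had the smallest adjusted p, 0.056, in the authors' deposited table.

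Of 47 neuropeptide genes, FMRFa rose by 0.36, and Ilp5 and NPF each fell by 0.35 on the log2 scale, in the authors' deposited table. Among 20 genes of transmitter synthesis and transport, Tdc1 (tyrosine decarboxylase) rose by 1.33 and prt (portabella, a vesicular transporter of the mushroom body) fell by 0.59 in the authors' deposited table. prt was also the only call among 21 mushroom body genes. The clock gene tim (timeless) rose by 0.73 in the authors' deposited table, 1 of 27 circadian and sleep genes. Arc1, an activity-regulated gene that encodes a capsid-forming protein, rose by 0.71 (implied standard error 0.10, adjusted p 7.2e-11) in the authors' deposited table. It was the only call among 14 activity-regulated genes, of which 5 were listed and 5 had a positive fold change in the authors' deposited table (Fisher's exact test, adjusted p = 0.0584, and 0.0486 within classes of mean count). Among progenitor genes of the authors' deposited table, l(1)sc fell by 0.49 (1 of 18 neuroblast genes) and the temporal factor cas rose by 0.28 (1 of 18). fzy and Top2 fell by 0.27 and 0.21 in the authors' deposited table, the only calls among 37 cell cycle genes over all genes or adjusted over the list alone. Listed cell cycle genes were 1 positive and 10 negative in the authors' deposited table (Fisher's exact test, adjusted p = 0.0435), a split no longer past the threshold within classes of mean count (adjusted p = 0.251). Of 23 Notch pathway genes 0 were called, with 1 positive and 5 negative in the authors' deposited table, and of 24 ecdysone response genes Eip55E fell by 0.27.

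The hemocyte genes NimC1 and Pxn rose by 1.01 and 1.25 on the log2 scale in the authors' deposited table, 2 of 16 hemocyte markers over all genes and 8 of 16 when adjusted over the list alone. Of those 16 markers 11 were listed in the authors' deposited table, where 3.43 would be listed by chance, and 11 had a positive fold change, between 0.96 and 1.54 (hypergeometric test, adjusted p = 0.00231, and Fisher's exact test of direction, adjusted p = 0.00248, or 0.0192 within classes of mean count). Both tests take the markers as independent, but markers of 1 cell type can vary together between pools, which these p do not measure. How much blood, muscle or eye disc tissue each pool held is not known here. Muscle genes had 3 of 20 members higher, over all genes and adjusted over the list alone, namely bt, Unc-89 and TpnC47D at 0.30, 0.64 and 0.69 in the authors' deposited table. Their 10 listed members in the authors' deposited table were positive in 10 cases (Fisher's exact test, adjusted p = 0.00392, and 0.0268 within classes of mean count). Of 22 eye disc genes gl (glass) rose by 0.94 in the authors' deposited table, and 6 of 6 listed members were positive (Fisher's exact test, adjusted p = 0.0435, and 0.233 within classes of mean count). Among 25 glial genes of the authors' deposited table, bnb rose by 0.26 while Eaat2, Ndae1 and Tret1-1 fell by 0.30, 0.27 and 0.26. Tsf1 (1 of 11 tracheal genes) rose by 0.36 and Idgf2 (1 of 15 fat body genes) by 0.63 in the authors' deposited table. Of 14 ring gland genes, 17 imaginal disc genes and 11 salivary gland genes 0 were called over all genes of the authors' deposited table, and 1 ring gland gene passed when adjusted over the list alone. The steroidogenic genes sad, phm, nvd, sro and spok were listed in the authors' deposited table with log2 fold changes from -0.43 to -0.24, a direction that did not pass (Fisher's exact test, adjusted p = 0.11, and 0.293 within classes of mean count).

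**Figure D2:**
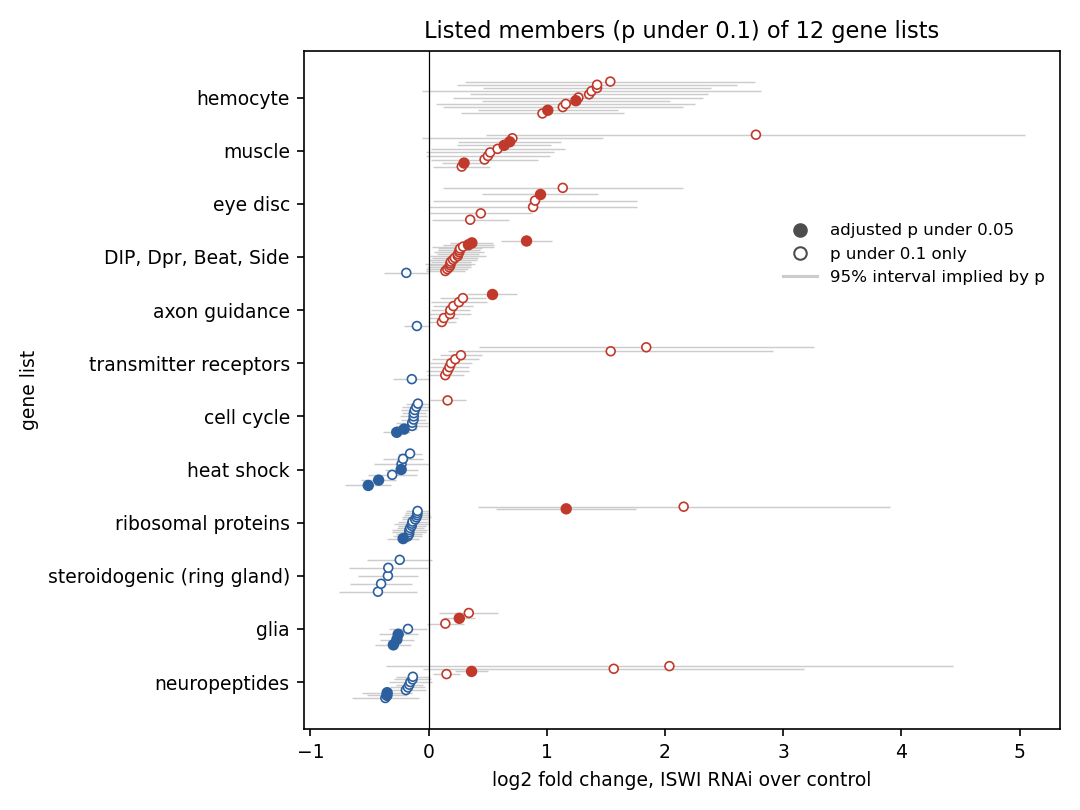
Log2 fold change (ISWI RNAi over control, horizontal axis) of the members of 12 gene lists (vertical axis) that the authors' deposited table lists at p under 0.1, with filled points for an adjusted p under 0.05 and grey lines for the 95% interval implied by p. The 11 hemocyte genes lie between 0.96 and 1.54, and 14 of 16 ribosomal protein genes lie below 0.

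Among proteins that work with ISWI, Chrac-16 fell by 0.46 in the authors' deposited table, so that with Iswi 2 of 9 genes of ISWI complexes were called, and 4 of 9 when adjusted over the list alone. Nurf-38, Acf, tou and E(bx) were listed at -0.16, -0.17, 0.25 and 0.18 in the authors' deposited table. Bap60 fell by 0.21 (1 of 16 genes of other remodelling complexes), pho by 0.26 (1 of 23 Polycomb and trithorax genes) and the replacement histone gene His3.3A by 0.26 (1 of 15 histone variant and chaperone genes) in the authors' deposited table. The small heat shock genes Hsp23, Hsp67Ba and Hsp27 fell by 0.42, 0.51 and 0.23 in the authors' deposited table, 3 of 20 heat shock genes over all genes and 6 when adjusted over the list alone. All 7 listed heat shock genes of the authors' deposited table were negative (Fisher's exact test, adjusted p = 0.0435), but at a median mean count of 19358 the split did not pass within classes of mean count (adjusted p = 0.302). Of 92 ribosomal protein genes, RpS19b rose by 1.16 and RpS2 fell by 0.22 in the authors' deposited table, and listed members were 2 positive and 14 negative (Fisher's exact test, adjusted p = 0.0241). Listed ribosomal protein genes had a median mean count of 22669 in the authors' deposited table, where most calls of any kind were lower, and within classes of mean count their direction did not pass (4.22 expected positive, exact test, adjusted p = 0.302). ND-AGGG and UQCR-11, respiratory chain subunits, fell by 0.72 and 0.41 in the authors' deposited table, 2 of 84 such genes. Both of these lie near the centromere of 3L. Among stress and immune genes of the authors' deposited table, Xrp1 rose by 0.30 (1 of 26) and nec, a serpin of the Toll pathway, fell by 0.60 (1 of 36). The 2 calls among 4 marker genes were y and v.

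The RNAs roX1 and roX2, which guide the dosage compensation complex to the male X chromosome, rose by 0.36 and 1.30 on the log2 scale in the authors' deposited table, with adjusted p of 0.006 and 4.7e-13. tra (transformer), of the sex determination pathway, fell by 0.39 in the authors' deposited table, and msl-2 was listed at 0.21 with an adjusted p of 0.11, among 13 dosage compensation and sex determination genes. The labels give no sex for the pooled larvae. Of the X-linked calls 21 were higher and 45 lower in the authors' deposited table, 31.8% higher against 47.1% of autosomal calls (Fisher's exact test, two-sided, p = 0.0236, and 0.00976 within classes of mean count). The median log2 fold change of X-linked calls lay at -0.30 in the authors' deposited table, with a difference of -0.12 from autosomal calls. Small changes are seldom called, so that difference depends on the mix of higher and lower calls and is no measure of a shift of all X-linked genes. Chromosome 4 had 1 higher call (bt) and 9 lower ones, among them pho, CR43425 and CR44029 (Fisher's exact test against all other calls, p = 0.0482, adjusted p = 0.497). In regions next to the centromeres, with approximate limits chosen after the values were seen, 2 calls were higher and 37 lower. Those regions were taken as 2L beyond 22 Mb, 2R before 5.4 Mb, 3L beyond 23 Mb, 3R before 4.2 Mb and X beyond 22 Mb, and no annotation of the heterochromatin border was used here. The adjusted p for the X among calls, over 23 lists, was also 0.497. Over all listed genes of the authors' deposited table, 117 X-linked genes were positive and 220 negative, 34.7% against 50.2% positive on the autosomes (Fisher's exact test, p = 1.3e-07). The adjusted p over 26 lists was 4.9e-06, and 7.4e-06 within classes of mean count. For chromosome 4 they were 9 positive and 20 negative in the authors' deposited table, with adjusted p of 0.148 and, within classes, 0.42. The tests by chromosome take genes as independent, while a shift shared by the genes of a chromosome would move many of them together. Each group is 1 genotype and the sex of the larvae is not given. The direction on the X therefore cannot be assigned to the knockdown rather than to the stocks or the sex of the pools.

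Adjusted over the list alone, counts differed from those over all genes for other lists too. In the authors' deposited table the genes passing were then 2 lower ones each for other remodellers, Polycomb and trithorax, and histone variants, 1 higher and 2 lower for transmitter synthesis, and 2 higher and 3 lower for both stress genes and glia. They were 3 higher and 1 lower for dosage compensation, 1 higher and 0 lower for ribosomal proteins, and 0 for immune genes. The X and chromosome 4 lists, which hold every annotated gene, kept 48 and 8 genes of the authors' deposited table.

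**Figure D3:**
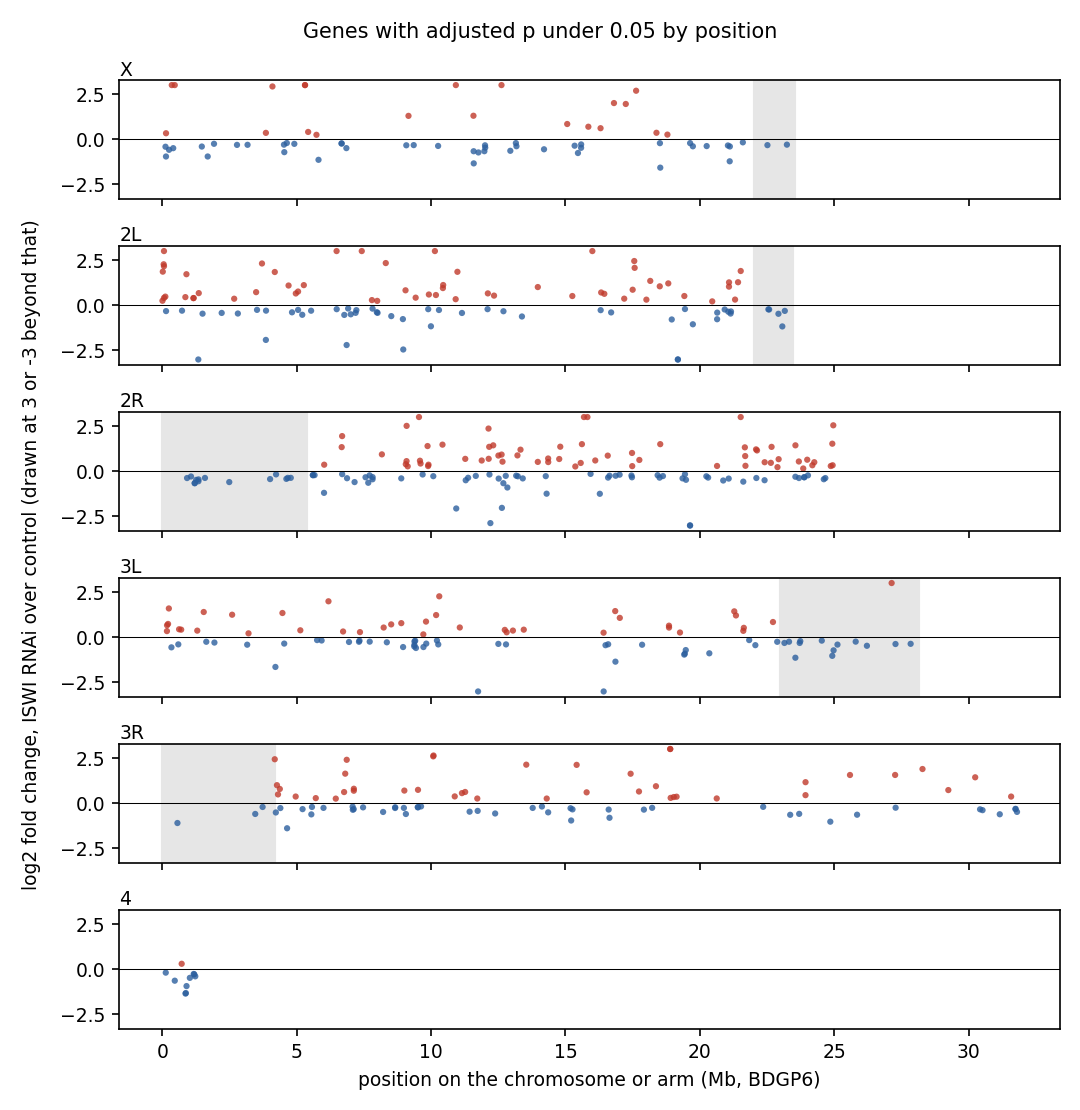
Log2 fold change (ISWI RNAi over control, vertical axis, drawn at 3 or -3 where larger) of the 501 genes with an adjusted p under 0.05 in the authors' deposited table by start position in Mb along chromosomes X and 4 and the arms of 2 and 3. Red points are higher and blue points lower, and grey bands mark the regions next to the centromeres, with 2 higher and 37 lower genes.

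Over 23 lists with at least 5 listed members and a call, 0 differed in direction from the other calls at an adjusted p under 0.05 (Fisher's exact test), and 2 did at an unadjusted p under 0.05, X and 4. The test could reach an unadjusted p under 0.05 for 3 of these lists (X, 4 and glia). The others hold too few calls, so it says nothing of their direction. The list directions given above as adjusted p under 0.05 rest on all genes listed at p under 0.1, a choice made after the table was seen, as was the test within classes of mean count. All list tests take genes as independent. Genes of a list, measured in the same 7 libraries, can vary together, so these p do not measure the spread between libraries and may be too small.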

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

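The alternatives on all listed genes, on classes of mean count and on the limits of the regions next to the centromeres were chosen after the results were seen. The 501 calls became 315 at an adjusted p under 0.01, 170 with a Bonferroni adjustment, and 121 with an absolute log2 fold change of at least 1, each a smaller set by construction. They became 687 at an adjusted p under 0.1 and 440 with a mean count of at least 50. The share of higher genes stayed between 40.5% and 47.6% except with the fold limit, where it was 73.6%, because the higher calls have lower mean counts and larger folds. With all listed genes in place of the calls, 10 lists in place of 0 differed in direction from the rest at an adjusted p under 0.05, with more genes in each list. Among calls only 3 lists could reach even an unadjusted p under 0.05. Within classes of mean count, 7 lists differed with all listed genes. There the cell cycle, heat shock, ribosomal protein and eye disc lists no longer passed and the activity-regulated list did. The chromosome 4 direction no longer passed an unadjusted p of 0.05 with a mean count of at least 50 (Fisher's exact test, p = 0.0544) or with all listed genes (p = 0.0911). The X and autosome difference kept its sign, at -0.09 with a mean count of at least 50 and -0.25 with all listed genes. Its size has no plain meaning, because genes with changes near 0 are mostly missing. Among all listed genes the autosomes had 977 positive and 968 negative, so their median of 0.10 lay at the edge of that gap. The difference depends on the mix of signs and is no measure of a shift of all X-linked genes. Calls next to centromeres were lower in 80.3% to 97.4% of cases over 5 alternatives, against 94.9% in the main setting. The lowest share came with limits 1 Mb farther from the centromere, so the pattern weakened beyond the limits chosen after the calls were seen. With limits 1 Mb nearer it was 95.8%. The remaining alternatives kept the chosen limits and do not test them. No paired analysis was possible because the columns carry no values per library. For the same reason other splits of the samples, leaving out each library, other normalisations and tests, and the unfiltered fit were not run, nor were the planned ranked list tests with their correlations and centring, or an adjustment recomputed over the listed genes. Low precision limits calls among genes with a mean count under 50, where the median implied standard error was 0.60 and the smallest log2 fold change called was 0.96. How much of that error comes from depth and how much from spread between pools is not known here.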

Other observations

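The germline lists, the neighbour comparisons and the regions next to the centromeres were chosen after the results were seen, as were all tests below except the one on reads running on from a neighbour. Genes known for germline functions moved in both directions in the authors' deposited table. Of 35 piRNA pathway genes 9 were called and of 28 meiosis genes 2, but the lists were compiled after the calls were seen, so a test of these counts against chance would be void. In the authors' deposited table piwi, CG13741, mael, Hen1 and cuff rose by 1.85, 2.51, 0.84, 0.69 and 0.59 on the log2 scale, and tej, SoYb, AGO3 and del had log2 fold changes of -1.24, -1.16, -1.13 and -0.46. The meiosis genes corolla and c(3)G rose, by 2.69 and 0.60 in that deposited table.

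The 11 listed hemocyte genes include lz, which is also in the eye disc list, and the other 5 hemocyte markers were not among the listed genes, so the folds of the listed ones do not stand for the whole list. Hml stood at 1.54 in the authors' deposited table with a mean count of 2069 and an implied standard error of 0.63, higher than 99.7% of listed genes with means of 1000 to 5000. Next to Iswi on 2R, CG17760 (8052 bp away) and nemy (18869 bp away) rose by 0.92 and 0.53 in the authors' deposited table.

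Calls next to the centromeres were mostly lower, within approximate limits set after the calls were seen, so no p is given. On the autosomes 35 of 37 such calls were lower in the authors' deposited table, among them lt, rl, Parp, Haspin, Myo81F and AGO3, against 190 of 388 autosomal calls elsewhere, and the 2 such calls on the X were lower too. Within these limits, expression level and gene length do not account for it as the whole cause. The log odds of a rise stayed at -2.90 (standard error 0.76) with mean count and length in the model, against -2.96 without. That standard error takes the limits as fixed beforehand and the genes as independent, so it does not measure how sure the pattern is. The pattern was not confined to noncoding and pseudogene models, since 100% of the protein-coding calls of these regions were lower (31 of 31). With 2 higher calls among all 39, that outcome was nearly fixed beforehand, so it is no separate test of repeat reads. Repeat reads counted to protein-coding models were not tested. Lower calls outnumbered higher ones on 5 of 5 chromosome arms, but by few calls on 3R (1 higher, 3 lower) and X (0 and 2). The counts were 0 and 5 on 2L, 0 and 14 on 2R, and 1 and 13 on 3L. Differences between the fly lines other than the knockdown cannot be told apart from an effect of the knockdown on heterochromatic genes. Each group is 1 genotype, and a modifier of heterochromatic expression could differ between them.

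Some of the largest changes came in neighbouring genes, mostly at low counts. Leaving out Iswi, 48 calls of the authors' deposited table had an absolute log2 fold change of at least 2, of which 27 had a mean count under 50 and 15 were noncoding RNAs, and 15 of the 48 lay within 20 kb of another, where 1000 random draws of calls gave 2.16 on average (95% of draws between 0 and 6). With a mean count of at least 50 it was 2 of 21, CR45054 and CR43459, at the upper end of the draws (0.378 on average, 95% between 0 and 2). That filter also drops pairs in which only a single member has a mean count under 50. An example is CG15930, 3242 bp from TrxT, which rose by 3.70 at a mean count of 33.6 in the authors' deposited table. In 4 of the 8 neighbouring pairs under 1000 bp lay between the genes, such as CG14297 and Rh2 with 81 bp and mean counts of 5.69 and 3.91 in that deposited table. Reads running on from a changed neighbour are argued against as the whole cause of the large changes by 19 of the 48 with no other listed gene within 20 kb moving the same way, but stay open for the grouped genes. Other differences between the fly lines, carried on shared stretches of chromosome, may account for the 15 grouped genes too, as may an effect of ISWI on whole regions, and these cannot be told apart because each group is 1 genotype. Differences between the lines stay equally open for large changes outside these groups, such as those of dsx-c73A and KFase.

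The rise of roX2 exceeded that of roX1 by 0.95 on the log2 scale (standard error 0.19), taking the errors implied by the authors' deposited table as independent. More male larvae in the knockdown pools as the whole cause would raise both male-limited RNAs by the same factor, so this difference argues against it, while a part of the rise common to both stays open. A difference in the sequence or activity of the region around roX2 remains possible, since 2 other calls within 20 kb of it, CR43217 and CR43215, had log2 fold changes of -0.66 and -1.33 in the authors' deposited table. An effect of ISWI on roX2 itself was not tested and may add to it.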
